A study of Homo sapiens with 6 samples.

How the data were processed

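Total RNA from the human cell line MHH-cALL4 was hybridised, as biotinylated cRNA, to 6 Affymetrix arrays, 3 of cells given DMSO and 3 of cells given 1 µM ruxolitinib for 12 h. One table with 1 column per array was used. The submitters' processing notes name Affymetrix Expression Console, Transcriptome Analysis Console and RMA, without versions, roles or order. RMA corrects background, normalizes between arrays and summarises probes on a log2 scale. The deposited values are log2 signals per transcript cluster (a set of probes for one transcribed locus), and this unit was read from their range of 1.99 to 19.9 over the 6 arrays. The genome build behind the clusters, the array annotation version and any filter are not given in the sources used here. Detection calls were not used here, so a level near the bottom of the range cannot be told from background, and a fold against such a level is likely to understate the change. For arrays there is no read depth, and their number limits the precision.

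The table held 135750 rows. The platform annotation gave 36176 of them exactly 1 gene symbol, 1119 several symbols and 98455 none. Rows with several symbols or none were left out of the gene-level tests. Symbols were updated through Entrez identifiers with a RefSeq table of the GRCh38.p14 assembly, which matched 25516 rows. This table also supplied gene biotypes and the order of neighbouring genes, and no coordinate is printed because the array's build is not stated. Each of 33616 genes was represented by its row with the highest mean over the 6 arrays. A further row existed for 1576 genes.

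Ruxolitinib was compared with DMSO with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, two-sided). The Benjamini-Hochberg adjusted p threshold was 0.05 over all genes, with no fold threshold. The median standard error of a log2 change was 0.200, and the median 95% interval reached 0.439 either side of the estimate, a factor of 1.36. On simulated data with the real genes' levels and spreads and 200 changed genes, run 10 times on 33616 genes, this fit recovered 0.600% of changes of 0.5, 26.8% of changes of 1, 64.8% of changes of 1.5 and 85.0% of changes of 2 on the log2 scale. Of its calls on those data, 3.38% were false, with members of a list that was also shifted by 0.3 not counted as false. The simulated genes share no signal on an array, so these percentages may not hold for the real arrays.

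Shifts of 33 gene lists were tested with camera, which asks whether a list's genes moved further in one direction than the other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. On the simulated data a list shifted by 0.3 was called in 10 of 10 runs, and 0 of 320 tests of other lists were called. Those simulated genes vary independently, so this leaves the correlation between real genes untested. Each list was tested again with the correlation estimated from the data. It was also tested with fry, which asks another question, whether a list's genes changed at all in one direction, without comparing them with the other genes. With the estimated correlation 0 of the 33 lists passed (camera, 7 at an unadjusted p under 0.05), the lowest adjusted p being 0.0992. With the preset correlation 21 passed, and with fry 9. Counts of list members use the adjustment over all genes unless they are given as adjusted over the list alone. Some genes stand in more than 1 list.

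The lists, the limma and set tests of the report, the rule for named genes and all but 5 of the alternatives were fixed before the data were examined. Those 5, chosen after seeing the data, were cyclic loess between arrays, the small RNA signal as a covariate, only protein-coding genes, the fit without DMSO replicate 1 and ruxolitinib replicate 3, and the count of neighbouring pairs with each array left out. The rule named the 12 highest and 12 lowest log2 changes among genes past the threshold with a mean above the median of all genes, no overlap between the groups and a symbol that is not that of an uncharacterised locus, a long intergenic RNA, a microRNA or other small RNA, an olfactory receptor or an open reading frame. It also named a fixed set of signalling, cell cycle and survival genes, and up to 4 members of each list with the smallest adjusted p. A gene of that fixed set is not reported here. CD69, GBP2, MYBBP1A, SRM, HSP90B1, CCNE2, CD38, BACH2, SH3BP5 and ZMAT3 are list members outside this rule and were chosen after their values were seen. Alternatives covered the spread model, filters on dim genes, the rows tested, scaling, thresholds, array weights, the replicate number and each array left out in turn. The replicate numbers shared by the groups were not treated as pairs.

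The titles of the ruxolitinib arrays give the line as MHH-cALL5, whereas the cell line field gives MHH-cALL4 for all 6 samples. The cell line field was followed. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.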

Results

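Gene expression was measured in MHH-cALL4, a B-cell precursor acute lymphoblastic leukaemia line of the Philadelphia chromosome-like subtype, known for high CRLF2 expression and active JAK2 signalling. The comparison asked which transcripts change when JAK signalling is blocked with ruxolitinib, an inhibitor of the JAK1 and JAK2 kinases. There were 3 arrays of cells given DMSO and 3 of cells given 1 µM ruxolitinib, all at 12 h. The titles of the ruxolitinib arrays give another line number, MHH-cALL5, than their cell line field. The median log2 signal over all rows lay between 4.51 and 4.59 on the 6 arrays. Correlations between arrays over 33616 genes were 0.990 to 0.994 within groups and 0.987 to 0.993 between groups. The first principal component (30.9% of the variance) separated the treatments, and the second (29.8%) set DMSO replicate 1 and ruxolitinib replicate 3 apart from the other arrays. These 2 arrays also had the highest mean signal over 215 rRNA, snRNA and snoRNA genes, at 8.48 and 8.45 on the log2 scale against 7.94 to 8.17 on the other 4.

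Ruxolitinib lowered many more transcripts than it raised. CISH, a feedback inhibitor induced by STAT5, fell the furthest, from 12.4 ± 0.26 to 5.87 ± 0.12 (log2 signal, mean ± SD, n = 3 per group; cluster TC0300011124.hg.1), a 91.8-fold difference. BCL6, a transcriptional repressor of B cells, rose the furthest, from 12.2 ± 0.44 to 15.0 ± 0.39 (cluster TC0300013471.hg.1), a 6.86-fold difference. At an adjusted p under 0.05 (limma), 350 genes were lower and 34 were higher. Of these, 36 were lower and 1 was higher by at least 4-fold. Protein-coding genes made up 321 of the lower and 29 of the higher genes. The median log2 change of all genes was -0.02. The total of 384 genes became 114 without DMSO replicate 2, 101 without ruxolitinib replicate 2, 227 without DMSO replicate 3, 246 without ruxolitinib replicate 3, 187 after quantile normalization and 2 without moderation of the spread, and the 34 higher genes became 11 without DMSO replicate 1 and 14 without ruxolitinib replicate 1. Under cyclic loess 59 genes were higher and 244 lower, without both arrays that stood apart the total was 319, and 92 of the 384 genes, 89 of them lower, were called whichever array was left out.

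**Figure D1:**
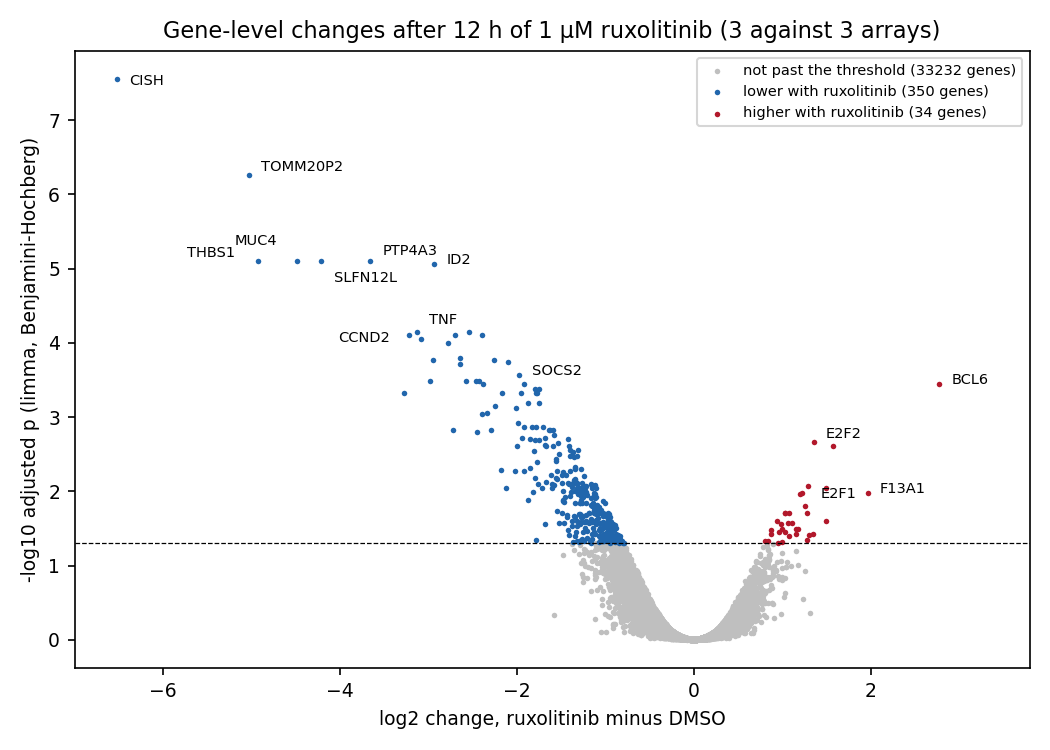
Each point is a gene, with its log2 change (ruxolitinib minus DMSO) on the x axis and -log10 of its limma adjusted p on the y axis; the dashed line is an adjusted p of 0.05. The 350 lower genes (blue) reach a log2 change of -6.52 (CISH), and the 34 higher genes (red) reach 2.78 (BCL6).

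Among the genes that fell furthest after CISH, THBS1, which encodes the matrix protein thrombospondin, fell by 4.93 ± 0.28 on the log2 scale (SE), and MUC4, a membrane mucin, fell by 4.49 ± 0.25. PTP4A3, a phosphatase, fell by 3.65 ± 0.20 from 15.0 ± 0.24 in DMSO (SD). The log2 change was -3.28 for CA6, a secreted carbonic anhydrase, -3.13 for the cytokine TNF, -2.98 for ENPP2, which encodes autotaxin, and -2.95 for TMEM154. SH3BP2, a signalling adaptor, fell by 3.08. SLFN12L fell by 4.21 ± 0.24 and TOMM20P2 by 5.03 ± 0.20. TOMM20P2 is a pseudogene that the RefSeq annotation places within the span of SLFN12L, so both signals may come from the same locus. A second, dimmer cluster of ENPP2 showed a change of -0.36 ± 0.24. The adjusted p (limma) of these genes lay between 5.54e-07 for TOMM20P2 and 0.000475 for CA6.

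The largest increases after BCL6 were smaller. F13A1, the A subunit of coagulation factor XIII, rose by 1.97 ± 0.31 on the log2 scale, DIPK1C by 1.58 ± 0.19, and NID2, a basement membrane protein, by 1.49 ± 0.23. The cell cycle transcription factors E2F2 and E2F1 rose by 1.36 ± 0.16 and 1.30 ± 0.19. ETS1, a lymphoid transcription factor, rose by 1.26 ± 0.21. DACT1 (1.28 ± 0.22), SLC8B1 (1.28 ± 0.26) and SLC35E3 (1.22 ± 0.19) also rose. Second, dimmer clusters of E2F1, DACT1 and SLC35E3 showed smaller changes of 0.40 ± 0.19, 0.67 ± 0.21 and 0.92 ± 0.18. The pseudogenes GTF2IP7 (1.35 ± 0.27) and AOX2P (1.31 ± 0.26) passed the test, but their signal may be shared with similar sequences. Of the 34 higher genes, only BCL6, DIPK1C and E2F2 were called whichever array was left out. Without DMSO replicate 2 or without ruxolitinib replicate 2, the other genes named here lost their call (adjusted p up to 0.219, limma).

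Among known STAT5 targets and feedback genes, 8 of 25 measured members fell, 1 rose and 16 did not pass the test. Besides CISH, the genes that fell were CCND2, which encodes cyclin D2 (log2 change -3.21 ± 0.24), the feedback inhibitors SOCS2 (-1.98 ± 0.17) and SOCS1 (-1.22 ± 0.22), the kinase gene PIM1 (-1.37 ± 0.17), MYC (-1.54 ± 0.22), LTB (-1.32 ± 0.19) and CD69 (-1.08). CCND3, which encodes cyclin D3, rose (1.18 ± 0.23). A second, dimmer CCND3 cluster showed 0.70 ± 0.23. SOCS3 (-0.02 ± 0.19), PIM2 (-0.18 ± 0.32), MCL1 (-0.15 ± 0.22), BCL2 (0.41 ± 0.26) and BCL2L1 (-0.66 ± 0.20, adjusted p = 0.219, limma) did not pass. SOCS3 was dim in both groups, at 3.64 and 3.63. Adjusted over the list alone, 11 members were lower and 1 was higher. The shift had a camera adjusted p of 3.54e-10, an adjusted p = 0.0992 with an estimated correlation and an adjusted p of 0.0108 with fry. Of the 6 fits that each leave out 1 array, CCND3, SOCS1 and CD69 kept their call in 1, LTB in 4 (lost without either replicate 2) and MYC in 5 (adjusted p = 0.062 without ruxolitinib replicate 2, limma). The count of lower members was 5 without DMSO replicate 2, 4 without ruxolitinib replicate 2 and 6 or 7 in the other fits.

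**Figure D2:**
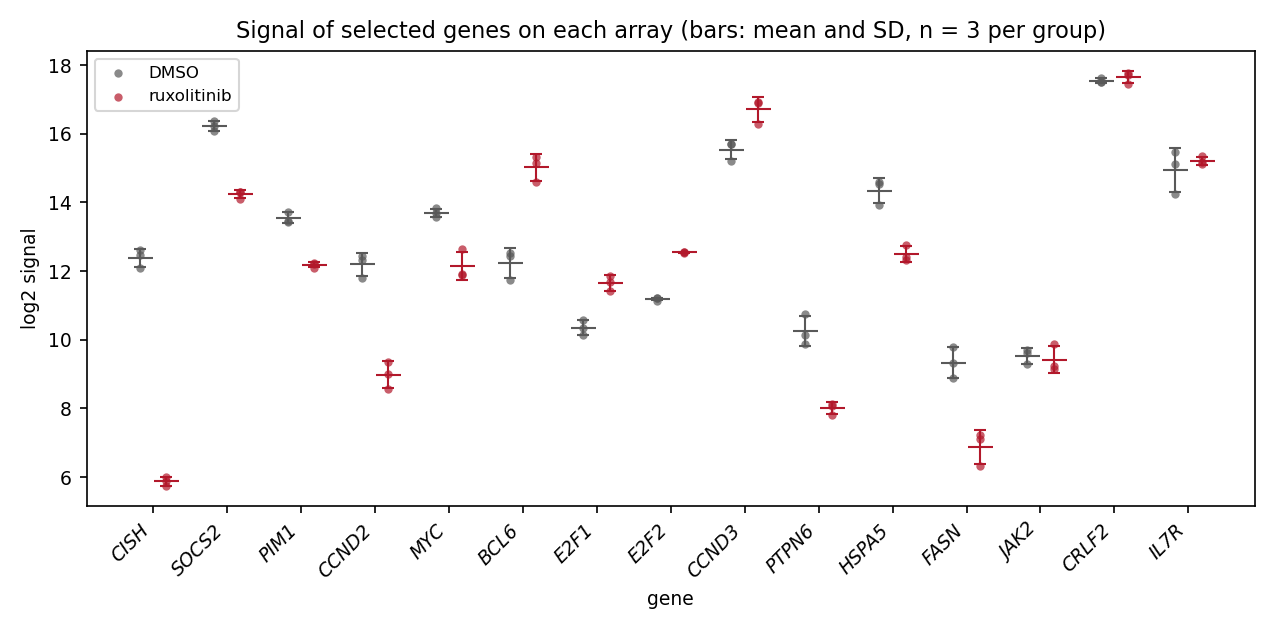
The log2 signal (y axis) of 15 genes (x axis) is shown on each of the 3 DMSO (grey) and 3 ruxolitinib (red) arrays, with the mean and SD of each group. CISH separates the groups most widely, at 12.4 against 5.87, while the groups overlap for JAK2, CRLF2 and IL7R.

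The receptor and kinases of the pathway themselves did not pass the test. The log2 change was 0.10 ± 0.17 for CRLF2, at 17.5 ± 0.07 in DMSO (SD), 0.27 ± 0.27 for IL7R, -0.06 ± 0.21 for JAK1, -0.11 ± 0.22 for JAK2 and -0.22 ± 0.21 for JAK3. STAT3 (-0.62 ± 0.20), STAT5A (0.39 ± 0.18) and STAT5B (0.35 ± 0.18) did not pass either. Second, dimmer clusters of CRLF2, JAK2 and STAT5B showed 0.06 ± 0.17, -0.42 ± 0.41 and 0.09 ± 0.24. Of the 37 measured JAK-STAT components 3 fell and 0 rose: PTPN6, which encodes the phosphatase SHP-1 (-2.24 ± 0.23), PTPRC, which encodes CD45 (-1.28 ± 0.24), and IL4R (-1.02 ± 0.21). Adjusted over the list alone, 8 were lower. The list was lower by camera (adjusted p = 0.000884; adjusted p = 0.253 with an estimated correlation), and this call was lost when only genes above the median level were tested (adjusted p = 0.109). Its median log2 change of -0.17 was a smaller fall than that of the housekeeping genes (-0.23). IL4R lost its call whichever array was left out (adjusted p up to 0.189, limma), and PTPRC in 4 of these 6 fits.

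Among 48 interferon-stimulated genes 5 fell and 0 rose: GBP5 (-1.08 ± 0.19), IRF9 (-1.09 ± 0.20), IFITM1 (-1.53 ± 0.28), SAMD9L (-0.93 ± 0.19) and GBP2 (-1.32). Adjusted over the list alone, 13 were lower. The list had a median log2 change of -0.30 and a camera adjusted p of 9.16e-08 (adjusted p = 0.328 with an estimated correlation). IRF9 lost its call whichever array was left out, as did LTA, and GBP5 and IFITM1 kept theirs in 2 of these 6 fits and SAMD9L and GBP2 in 1. The count of lower interferon-stimulated genes was 0 without DMSO replicate 2, DMSO replicate 3 or ruxolitinib replicate 2. It was 5 without DMSO replicate 1, 3 without ruxolitinib replicate 1 and 2 without ruxolitinib replicate 3. Among NF-kB targets the cytokines TNF, LTA (-1.02 ± 0.18) and LTB and the inhibitor TNFAIP3 (-1.40 ± 0.19) fell, 4 of 32 members with 0 rising and 5 lower adjusted over the list alone. The NF-kB list did not pass (camera adjusted p = 0.0908). Of 37 MAPK feedback and immediate early genes, EGR1 (-2.01 ± 0.21) and MYC fell and 0 rose, with 7 lower and 1 higher adjusted over the list alone. DUSP6, a feedback phosphatase of ERK, had a change of -0.28 ± 0.22 and did not pass. That list was lower by camera (adjusted p = 0.00421; adjusted p = 0.411 with an estimated correlation), and the call was lost without ruxolitinib replicate 3 (adjusted p = 0.122) and without both arrays that stood apart (adjusted p = 0.285).

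Among 41 measured MYC targets 15 fell and 0 rose, and 26 were lower and 1 higher adjusted over the list alone. The nucleolar factors NOP16 (-1.92 ± 0.21) and IMP4 (-1.62 ± 0.19), the mitochondrial chaperonin HSPE1 (-1.68 ± 0.21), MYBBP1A (-1.67) and SRM, which encodes spermidine synthase (-2.02), were among them. Among 41 ribosome biogenesis factors 13 fell and 0 rose, and 32 were lower adjusted over the list alone, with the smallest adjusted p (limma) for DDX21 (-1.37 ± 0.20), UTP15 (-1.17 ± 0.17), RRP15 (-1.11 ± 0.17) and NOB1 (-1.25 ± 0.19). The median log2 change was -0.72 for the first list and -0.75 for the second, and the lists share 4 genes. Their camera adjusted p was 1.99e-25 and 2.07e-31, each with an adjusted p = 0.0992 with an estimated correlation. The count of lower MYC targets was 7 without DMSO replicate 2, 5 without ruxolitinib replicate 2, 9 without DMSO replicate 3 and 8 without ruxolitinib replicate 3, and SRM kept its call in 5 of the 6 fits that each leave out 1 array. The count of lower ribosome biogenesis factors was 7 without DMSO replicate 3, and all 13 lost their call without DMSO replicate 2 or without ruxolitinib replicate 2 (adjusted p up to 0.0675 for the 4 named here, limma). Of 31 cytosolic ribosomal protein genes 0 passed the test in either direction (limma; 1 lower and 0 higher at an unadjusted p under 0.05), also adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.0079; adjusted p = 0.616 with an estimated correlation), and that call was lost without DMSO replicate 3 (adjusted p = 0.0877), without ruxolitinib replicate 3 (adjusted p = 0.403) and without both arrays that stood apart (adjusted p = 0.285).

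Several chaperone genes fell. In the unfolded protein response list 7 of 22 genes fell and 0 rose, among them HSPA5, which encodes BiP (-1.85 ± 0.22), MANF (-1.38 ± 0.18), CALR (-1.35 ± 0.18), HSP90B1 (-1.34) and the transcription factor XBP1 (-1.15 ± 0.19). Adjusted over the list alone, 13 were lower (camera adjusted p = 2.81e-12; adjusted p = 0.0992 with an estimated correlation). In the heat shock list 4 of 18 fell and 0 rose: HSPE1, FKBP4 (-1.31 ± 0.16), HSP90AB1 (-0.95 ± 0.17) and HSPD1 (-0.95 ± 0.19). Adjusted over the list alone, 6 were lower (camera adjusted p = 9.16e-08; adjusted p = 0.228 with an estimated correlation). Of the 6 fits that each leave out 1 array, HSP90B1, HSP90AB1 and HSPD1 kept their call in 1 and XBP1 in 2. The count of lower unfolded protein response genes was 3 without DMSO replicate 2, DMSO replicate 3 or ruxolitinib replicate 2, and 4 without ruxolitinib replicate 1 or 3.

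FASN, the fatty acid synthase, fell by 2.45 ± 0.28 on the log2 scale, ACACA, an acetyl-CoA carboxylase, by 1.79 ± 0.18 and the elongase ELOVL6 by 1.12 ± 0.22, making 3 of 15 fatty acid synthesis genes lower, 0 higher, and 4 lower adjusted over the list alone (camera adjusted p = 1.11e-05; adjusted p = 0.0992 with an estimated correlation). A second, dimmer ACACA cluster showed 0.05 ± 0.30. In the cholesterol synthesis list CYP51A1 (-1.30 ± 0.20), DHCR7 (-1.43 ± 0.26) and NSDHL (-0.85 ± 0.18) fell, 3 of 23 with 0 rising and 5 lower adjusted over the list alone (camera adjusted p = 2.13e-07; adjusted p = 0.328 with an estimated correlation). Of 26 glycolysis genes only the hexokinase gene HK2 (-1.18 ± 0.25) fell and 0 rose. LDHA (-0.82 ± 0.18) and ENO1 (-0.70 ± 0.19) did not pass over all genes but did adjusted over the list alone, where 7 were lower and 1 higher (camera adjusted p = 3.66e-05; adjusted p = 0.328 with an estimated correlation). A second, dimmer ENO1 cluster showed -1.38 ± 0.40. Of 40 ATF4 response genes DDIT4, an inhibitor of mTORC1 (-2.13 ± 0.32), and CBS (-1.82 ± 0.28) fell and 0 rose, with 10 lower adjusted over the list alone (camera adjusted p = 5.14e-07; adjusted p = 0.328 with an estimated correlation). A second, dimmer CBS cluster showed -1.20 ± 0.30. For 45 oxidative phosphorylation genes the median was -0.41. None passed over all genes (limma; 19 lower and 0 higher at an unadjusted p under 0.05) and 5, including CYCS and COX5A, were lower adjusted over the list alone (camera adjusted p = 7.22e-11; adjusted p = 0.328 with an estimated correlation). NSDHL lost its call whichever array was left out, ELOVL6 and HK2 kept theirs in 1 of these 6 fits, DHCR7 in 2, and CYP51A1, DDIT4 and CBS in 4 (lost without either replicate 2).

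**Figure D3:**
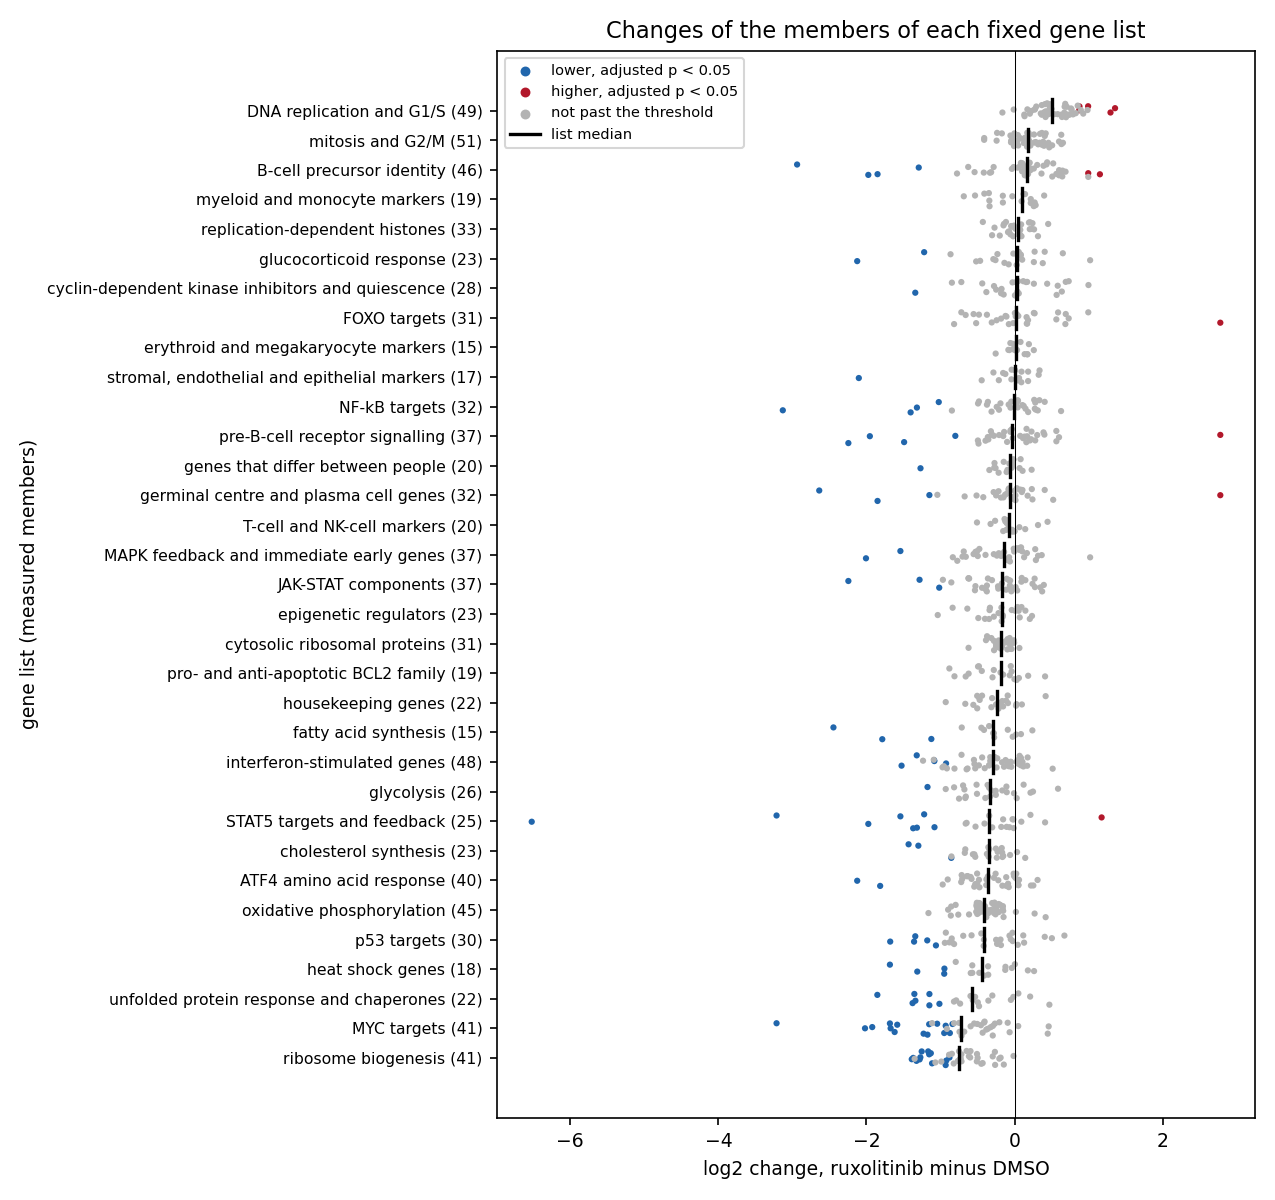
Each point is the log2 change (x axis, ruxolitinib minus DMSO) of a member of one of the 33 gene lists (y axis, with the number of measured members), coloured blue if lower and red if higher at an adjusted p under 0.05, with the list median as a black bar. Medians run from -0.75 for ribosome biogenesis to 0.50 for DNA replication and G1/S.

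Among genes of DNA replication and the G1/S transition, E2F2, E2F1, CDC45 (0.87 ± 0.17), EXO1 (0.88 ± 0.17) and CCNE2, which encodes cyclin E2 (0.99), rose, making 5 of 49 members higher and 0 lower, and 24 were higher and 0 lower adjusted over the list alone. The list median was 0.50 (camera adjusted p = 1.41e-28; adjusted p = 0.0992 with an estimated correlation; fry adjusted p = 0.0366). Without both arrays that stood apart the median was 0.42. CDC45 and EXO1 lost their call whichever array was left out (adjusted p up to 0.187, limma), CCNE2 kept it in 1 of these 6 fits, and E2F1 in 4 (lost without either replicate 2). Of 51 mitosis and G2/M genes 0 passed in either direction (limma; 6 higher and 1 lower at an unadjusted p under 0.05), also adjusted over the list alone. Their median was 0.18 (camera adjusted p = 1.11e-05; adjusted p = 0.351 with an estimated correlation), with MKI67 at 0.37 ± 0.17 and NCAPG at 0.65 ± 0.23. The 33 replication-dependent histone genes had a median of 0.05 and 0 passed in either direction, also adjusted over the list alone (limma; 1 lower and 0 higher at an unadjusted p under 0.05; camera adjusted p = 0.333). The histone list passed, as higher, without DMSO replicate 1 (adjusted p = 0.00184) and without both arrays that stood apart (adjusted p = 0.00475, median 0.18). CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.34 ± 0.18 on the log2 scale and was the only one of 28 genes of cell cycle inhibition and quiescence past the threshold. Adjusted over the list alone, 4 of these were higher and 3 lower, and CDKN1B (0.17 ± 0.20) did not pass. The list had a camera adjusted p of 0.400.

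Genes of B cells fell and rose. ID2, an inhibitor of E proteins (-2.94 ± 0.17), SOCS2, MS4A1, which encodes CD20 (-1.85 ± 0.25), and IRF8 (-1.29 ± 0.20) fell, and CD38 (0.99) and the repressor BACH2 (1.15) rose, so that 4 of 46 B-cell precursor genes were lower and 2 higher (5 and 8 adjusted over the list alone). IGLL1, which encodes a part of the surrogate light chain, had a change of 0.31 ± 0.43 with an SD of 0.74 in DMSO and 0.90 with ruxolitinib. RAG1 (0.56 ± 0.18, adjusted p = 0.236, limma) and RAG2 (1.00 ± 0.25, adjusted p = 0.108, limma) did not pass over all genes and did adjusted over the list alone. The list was higher by camera (adjusted p = 0.0086; adjusted p = 0.446 with an estimated correlation), and that call was lost without ruxolitinib replicate 1 (adjusted p = 0.16). In the pre-B-cell receptor list BCL6 rose and CR2 (-1.95 ± 0.19), PTPN6, BANK1 (-1.49 ± 0.22) and SH3BP5 fell, 1 higher and 4 lower of 37 (camera adjusted p = 0.655), with the same numbers adjusted over the list alone. A second, dimmer BANK1 cluster showed -0.34 ± 0.19. Among 32 germinal centre and plasma cell genes BCL6 rose and JCHAIN, the joining chain of secreted antibodies (-2.64 ± 0.22), MS4A1 and XBP1 fell (camera adjusted p = 0.253), with 1 higher and 4 lower adjusted over the list alone. Of 31 FOXO targets BCL6 alone passed (5 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.293), and under quantile normalization that list passed as higher (adjusted p = 0.0428). Of the 6 fits that each leave out 1 array, SH3BP5 kept its call in 0, BACH2 in 1, CD38 and XBP1 in 2, IRF8 in 4 and BANK1 in 5.

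None of 19 BCL2 family members passed over all genes (limma; 5 lower and 0 higher at an unadjusted p under 0.05), and BAX (-0.88 ± 0.22), BMF (-0.62 ± 0.18) and BCL2L1, 3 in all, were lower adjusted over the list alone. BCL2L11, which encodes BIM, had a change of 0.03 ± 0.20. The family was lower by camera (adjusted p = 0.00846; adjusted p = 0.331 with an estimated correlation), and the call was lost without DMSO replicate 3 (adjusted p = 0.0877), without ruxolitinib replicate 3 (adjusted p = 0.0931) and above the median level (adjusted p = 0.0687). Among 30 p53 targets CDKN1A, AEN (-1.36 ± 0.20), FBXW7 (-1.18 ± 0.21), TIGAR (-1.68 ± 0.32) and ZMAT3 (-1.06) fell and 0 rose, with 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.16e-08; adjusted p = 0.0992 with an estimated correlation). FBXW7 and TIGAR kept their call in 2 of the 6 fits that each leave out 1 array, and ZMAT3 in 1. TIGAR lies next to CCND2 in the RefSeq annotation. Of 23 glucocorticoid response genes DDIT4 and SOCS1 fell, with 3 lower adjusted over the list alone. That list had a median of 0.03 and a mean of -0.12, opposite in sign, and did not pass (camera adjusted p = 0.643). Of 23 epigenetic regulators 0 passed over all genes (limma; 4 lower and 0 higher at an unadjusted p under 0.05) and 1, DNMT3A (-1.04 ± 0.26), was lower adjusted over the list alone. The list was lower by camera (adjusted p = 0.0291; adjusted p = 0.328 with an estimated correlation), and the call was lost without DMSO replicate 1 (adjusted p = 0.0516), DMSO replicate 2 (0.0672), ruxolitinib replicate 2 (0.0551) or ruxolitinib replicate 3 (0.14).

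Lists of markers of other cell types did not pass the test. Median levels were 4.52 for 20 T-cell and NK-cell markers, 5.04 for 19 myeloid markers, 4.65 for 15 erythroid and megakaryocyte markers and 5.70 for 17 stromal, endothelial and epithelial markers, against 5.25 for all genes. Their camera adjusted p values were 0.655, 0.926, 0.400 and 0.637. For the myeloid list the median (0.09) and mean (-0.04) differ in sign, and for the stromal list likewise (0.01 and -0.12). PDGFRB, a receptor kinase gene, was the only member of these 4 lists to pass (-2.10 ± 0.18, from 8.75 ± 0.05 in DMSO), also adjusted over the lists alone. Of 20 genes that often differ between people 1 passed, CHI3L2 (-1.27 ± 0.17; camera adjusted p of the list 0.288), also adjusted over the list alone. That list passed, as lower, without DMSO replicate 1 (adjusted p = 0.0306) and without ruxolitinib replicate 1 (adjusted p = 0.0138). None of 22 housekeeping genes passed (limma; 5 lower and 0 higher at an unadjusted p under 0.05), also adjusted over the list alone. Their median was -0.23 (camera adjusted p = 0.00271; adjusted p = 0.495 with an estimated correlation), and this call was lost without ruxolitinib replicate 3 (adjusted p = 0.119) and above the median level (adjusted p = 0.0703). Smaller median falls were seen for JAK-STAT components (-0.17), MAPK feedback (-0.14), the BCL2 family (-0.19), epigenetic regulators (-0.17) and ribosomal proteins (-0.18). The camera calls of those lists therefore cannot be told from a fall that housekeeping genes shared.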

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

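Rows of the table outside the gene-level tests also held signal. In fits of their own, 8 of 1119 rows with several gene symbols and 7 of 98455 rows with no symbol passed an adjusted p of 0.05 (limma), all of them lower with ruxolitinib and reaching log2 changes of -4.78 and -4.90. At an unadjusted p under 0.05 there were 123 and 4565 rows, where 56.0 and 4923 would pass by chance. These rows are not named here. The tests by the histones and the genes that differ between people were chosen after the results they bear on had been seen, and the fits under cyclic loess, with the small RNA covariate and without DMSO replicate 1 and ruxolitinib replicate 3 after the data had been seen.

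The excess of lower over higher genes (350 against 34) was weighed against 2 technical explanations. An intensity-dependent shift left by the normalization would bring the directions closer under cyclic loess between arrays. They came closer in part, with 80.5% of 303 calls lower (244 against 59), against 91.1% of 384. Such a shift may therefore carry part of the excess, though most calls stayed lower under cyclic loess. The small RNA signal was high on DMSO replicate 1 and ruxolitinib replicate 3, an array of each group. A signal so balanced between the groups could hardly favour lower calls, so a covariate for it cannot decide the question. With that covariate 92.7% of calls were lower (534 against 42). Inhibition of JAK-STAT signalling, the explanation that the design names, was not tested as a cause of the excess and stays open.

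Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one itself, reached its count of 384 genes, the highest other split called 2, and 10 splits are too few for a share under 0.05. That highest other split put DMSO replicates 1 and 2 with ruxolitinib replicate 3, and it had 3646 genes at an unadjusted p under 0.05 against 3205 in the real split.

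The rise of G1/S genes beside the fall of MYC targets was weighed next (each list had an adjusted p = 0.0992 with an estimated correlation). The G1/S rise remained without the arrays that stood apart, with a median of 0.42 on the log2 scale against 0.50 with all arrays. Those arrays came from different groups, so a signal they share could hardly raise the list. This check therefore cannot decide on such a signal. Under cyclic loess the G1/S median was 0.64, which argues against an intensity-dependent shift for the G1/S rise only. Genes above the median level had a median change of -0.07, so removing such a shift was likely to raise this bright list. Both checks were set for the G1/S list only. The MYC target list kept its camera call, as lower, in both fits at the preset correlation. The size of its fall there was not weighed against these explanations. A larger share of cells in S phase as the whole cause would raise replication-dependent histones about as far. The upper end of the 95% bootstrap interval of their median was 0.0748. That interval resampled the 33 genes and not the arrays, so it leaves out the spread between arrays and cannot decide the question. The highest histone median under any alternative was 0.18, without both arrays that stood apart, outside the interval and below the G1/S median of 0.42 there. A candidate explanation that stays open, and was not tested, is altered E2F activity. E2F1 and E2F2 rose, but both are members of the G1/S list itself, and E2F1 lost its call without either replicate 2. Cell cycle phases were not measured here.

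The titles of the ruxolitinib arrays name another line number than their cell line field. If those arrays held another person's cells, several of the 20 fixed genes that differ between people would change by more than 2 on the log2 scale, and 0 did, the largest change being 1.27 in size (CHI3L2) and 15 of the 20 lying above the median level. The correlations between groups (0.987 to 0.993) nearly covered the range within groups (0.990 to 0.994). That several genes would change so far was presumed and not calibrated on other lines. As a list these genes passed as lower without DMSO replicate 1 (camera adjusted p = 0.0306), without ruxolitinib replicate 1 (0.0138) and with the small RNA covariate (0.0433). The values thus argue against a different line only as far as that presumption holds, and a typing error in the titles may explain the number.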

How the results depend on the processing

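The count of 384 changed genes (34 higher, 350 lower) varied between the alternatives, while its direction did not. Lower genes made up 80.5% to 97.0% of calls in every gene-level alternative except the fit without moderation. The count was 327 with an intensity trend, 394 with robust moderation, 419 above the median level and 416 above the 25th percentile of level. Without moderation of the spread, 2 genes passed (1 higher, 1 lower), with 2747 at an unadjusted p under 0.05. Testing every row of the table gave 104 (6 higher, 98 lower), quantile normalization 187 (21 and 166), an adjusted p under 0.01 140 (5 and 135), and only protein-coding genes 597 (64 and 533). With the small RNA signal as a covariate 534 were lower, and under cyclic loess 59 were higher; these 2 alternatives, the protein-coding genes and the fit without DMSO 1 and ruxolitinib 3 were chosen after seeing the data. Leaving out each array in turn gave 101 to 291 genes (3 to 28 higher, 98 to 280 lower), the lowest without ruxolitinib replicate 2 and without DMSO replicate 2 (114). All 384 genes kept their direction in these 6 fits, which was nearly bound to happen for genes called on the same arrays. Of the 384, 92 kept their call in every fit and 72 lost it in every fit. Of the 77 called genes that the rule named, 37 kept it in every fit. The replicate numbers did not pair the arrays: deviations from the group means correlated at -0.21, -0.08 and -0.40 for numbers 1, 2 and 3, and 0 of 6 arrays came closest to the array of its own number in the other group. With the replicate block, 122 genes were called (6 higher, 116 lower), no list changed its call and 32 of the 77 called named genes did not pass. Of those 77, 21 did not pass under quantile normalization, 12 without DMSO 1 and ruxolitinib 3, 7 under cyclic loess, 4 with an intensity trend, 2 with the mean of a gene's clusters, and 16 to 39 with each array left out. No list call and no named gene call turned its direction in any alternative run; 23 of 495 list values and 21 of 2198 named gene values did so with neither value past the threshold. With an estimated correlation all 21 called lists lost their call: STAT5 targets, MYC targets, ribosome biogenesis, G1/S, p53 targets, fatty acid synthesis and the unfolded protein response (0.0992 each), heat shock (0.228), JAK-STAT components (0.253), interferon-stimulated genes, cholesterol synthesis, glycolysis, ATF4 response, oxidative phosphorylation and epigenetic regulators (0.328 each), the BCL2 family (0.331), mitosis (0.351), MAPK feedback (0.411), B-cell precursor identity (0.446), housekeeping genes (0.495) and ribosomal proteins (0.616). With fry the adjusted p was 0.125 for interferon-stimulated genes, cholesterol synthesis, glycolysis, the ATF4 response and epigenetic regulators, 0.149 for MAPK feedback and oxidative phosphorylation, 0.161 for the BCL2 family, 0.301 for ribosomal proteins, mitosis and housekeeping genes, and 0.837 for B-cell precursor identity. Above the median level, JAK-STAT components (0.109), ribosomal proteins (0.163), the BCL2 family (0.0687), epigenetic regulators (0.271) and housekeeping genes (0.0703) lost their call. Quantile normalization ended the call of epigenetic regulators (0.275) and made one of FOXO targets (0.0428, higher). Cyclic loess ended that of epigenetic regulators (0.274) and made those of FOXO targets (0.0412) and histones (0.0431). Without DMSO 1 and ruxolitinib 3, ribosomal proteins (0.285), MAPK feedback (0.285) and epigenetic regulators (0.171) lost theirs and histones gained one (0.00475). With the small RNA covariate, genes that differ between people passed (0.0433, lower). With each array left out, the adjusted p ranged from 0.000595 to 0.16 for B-cell precursor identity, 0.00135 to 0.403 for ribosomal proteins, 0.00937 to 0.14 for epigenetic regulators, 0.0138 to 0.919 for genes that differ between people, 2.22e-05 to 0.119 for housekeeping genes, 0.000372 to 0.122 for MAPK feedback, 0.000987 to 0.0931 for the BCL2 family and 0.00184 to 0.517 for histones. The cause of these changes was not tested. Without detection calls, the signal over background behind each fold is unknown.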

Other observations

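Several genes outside the fixed lists, chosen here after their values were seen, fell with ruxolitinib; the test of TOMM20 and the count of neighbouring pairs with each array left out were likewise chosen after the results they bear on were seen. Among them were the chemokine genes CCL2 (log2 change -2.70 ± 0.20, SE) and CCL17 (-1.41), the chemokine receptor gene CCR1 (-1.19), the leukotriene pathway genes ALOX5AP (-1.94) and CYSLTR1 (-1.99), CASP1 (-1.42), TLR7 (-1.72), the interleukin-1 receptor subunit gene IL1RAP (-1.60), and the growth factor genes TGFB1 (-1.47), VEGFA (-1.34) and HBEGF (-1.77). The PI3K gamma regulatory subunit genes PIK3R5 (-1.75) and PIK3R6 (-2.33), VSIR, which encodes the checkpoint protein VISTA (-1.78), SIRPA (-1.40) and CNR2 (-1.26) also fell. The sialyltransferase gene ST8SIA4 (0.96) and the calcineurin regulator gene RCAN1 (1.03) rose. Each passed the adjusted p threshold of 0.05 (limma), and no test of these genes as a list was run, since they were picked for their change. Of the 6 fits that each leave out 1 array, ST8SIA4 kept its call in 0, CCR1 in 1, RCAN1 in 2, TGFB1 in 4 and CNR2 in 5.

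Some called genes lay next to each other. Along the RefSeq order of 17340 protein-coding genes, 23 adjacent pairs were called in the same direction, all lower, against a mean of 5.97 over 10000 random placements of the 350 calls and a 95th percentile of 10 (permutation p = 1e-04, one-sided, the smallest these placements can give). The placements drew on dim genes as well, whereas 373 of all 384 called genes lay above the median level. If expressed genes lie together along chromosomes, the random mean is too low and this p-value overstates the clustering. The same limit holds for the fits that leave out an array. The pairs include CISH with MAPKAPK3 (-2.58), CCND2 with TIGAR (-1.68), SOCS2 with CRADD (-1.28), LTA with TNF and TNF with LTB, PIK3R6 with PIK3R5, and PIM1 with both of its neighbours, FGD2 (-1.12) and TMEM217 (-1.14). The count of such pairs was 13 without DMSO replicate 1, 4 without DMSO replicate 2, 7 without DMSO replicate 3, and 14, 4 and 10 without ruxolitinib replicates 1, 2 and 3 (12 of the 14 being among the 23), against means of 0.472 to 3.73 over random placements of those calls (permutation p from 1e-04 to 0.0031). In 4 of the pairs (CISH with MAPKAPK3, PIK3R6 with PIK3R5, IFT57 with HHLA2 and ENTPD6 with PYGB) both genes kept their call whichever array was left out. Of those 6 fits, LTA and TMEM217 kept their call in 0, FGD2 in 1, TIGAR in 2, CRADD in 3 and LTB in 4. The spans of 1 of the pairs, CISH and MAPKAPK3, overlap in the annotation, so their signals could be shared there. Why neighbouring genes fell together was not tested.

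The fall of the pseudogene TOMM20P2 (-5.03) may be a signal of SLFN12L, in whose span it lies, and this was not tested further. Cross-hybridisation from its parent gene was argued against, since TOMM20 itself had a change of -0.36 ± 0.18, a difference of 4.67 ± 0.27 from TOMM20P2.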
